A study of Mus musculus with 2 samples.

How the data were processed

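Bone marrow of mice (age 8 weeks, per the labels) was grown into macrophages in medium conditioned by L929 cells, a mouse fibroblast line that secretes macrophage colony-stimulating factor. Total RNA was labelled with biotin and hybridised to an Affymetrix 1.0 ST array, which carries probes along the whole transcript of each gene. There were 2 arrays, 1 of control macrophages and 1 of macrophages labelled beta-catenin deficient. The mouse line, the deleted exons, the Cre driver and the number of animals per culture are not given in the sources used here.

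The deposited table held 1 log2 value per transcript cluster and array. Per the submitters' processing notes the values came from RMA, a method that corrects background, quantile-normalizes probes between arrays and summarises the probes of a transcript cluster. The RMA version, its settings and any filter on rows are not given in the sources used here. The table had 25917 rows. Values of the control column were written with up to 10 significant digits and those of the other column with up to 6, and no label says whether both columns came from 1 RMA run or whether a column is the value of a single hybridisation or a mean of several. Each column is called an array here because the labels give 1 sample per column. Scale was taken as log2 from the range of the values, 2.12 to 14.1. The difference was computed as the array labelled deficient minus control.

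Rows were named through GEO's platform annotation. A single gene symbol was given for 21632 rows, several symbols for 1560 and none for 2725. Of the single-symbol rows, 21537 had their Entrez ID in a RefSeq gene table of the assembly GRCm38.p6, and the update through that table changed 0 symbols. Symbols in the fixed gene lists were matched directly or through a synonym that pointed to 1 gene. No genome sequence was used, and no coordinates are printed, because the build behind the array's annotation is not given in the sources used here. Where a gene had several transcript clusters (947 of 19871 genes), the cluster with the highest mean level was kept.

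With 1 array per group there are no residual degrees of freedom. No p-value, standard error or count of significant genes was computed. Every value below is the value of 1 deposited column or the difference of 2, and no difference could be set against a spread between cultures. Genes were counted by a rule of size fixed before the data were examined: a difference of at least 2-fold (1 on the log2 scale) and the higher of both values at or above a floor of 7.28, the median of all values in the table. The floor left 10658 genes. RMA values carry no detection call and no read depth, so the floor is a rule about brightness and not a proof of expression. The number of arrays limits the precision.

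Also fixed before the data were examined were 40 gene lists. For each list the median difference of the members at or above the floor was set among the medians of 10000 random lists of the same size, drawn from the genes at or above the floor and matched on mean level in 20 bins. A list is said to stand apart when its median lies at or below percentile 2.5 or at or above percentile 97.5. This describes these 2 arrays. It is not a test between conditions, about 2 of 40 lists would stand apart by chance, and random lists do not keep the co-expression of real ones. Members at least 1.5-fold higher or lower were counted.

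The rule for named genes, also fixed beforehand, takes Ctnnb1, the 12 genes with the largest positive and the 12 with the largest negative difference, and the 2 highest and 2 lowest members of each list described. For the cadherin and catenin, Wnt target, integrin, focal adhesion, chemokine and TGF-beta lists it takes 3 and 3. Predicted and unnamed gene models were passed over among the 24 leading genes (0 among the higher and 3 among the lower). Genes outside the rule whose values are given are marked as chosen after their values were seen.

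The procedure was tested on simulated data with the 10658 genes of this comparison and 200 changed genes. It recovered 100.0% of the 4-fold changes and 56.0% of the 2-fold changes, with 65 unchanged genes past 2-fold. Of 400 unchanged lists of 25 genes, 5.25% stood apart, and of 100 lists raised by 0.5 all (100.0%) did. The simulated noise had an SD of 0.37, scaled from the median absolute deviation of the differences across genes, which gives little weight to the tails. That spread holds real changes as well as noise. The plain SD of the same differences was 0.48. Larger noise would put more unchanged genes past 2-fold, so the 65 is not an upper bound. It was independent between genes and the same at each level. The 5.25% therefore does not carry over to lists of co-expressed genes, and lists of other sizes were not simulated.

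Alternatives set beforehand were no floor, a floor at the 75th percentile, a floor on the mean, centring, quantile normalization of the 2 columns, subtraction of a loess curve of the difference on level (span 0.4), the mean over transcript clusters, each row counted separately, thresholds of 1.5-fold and 3-fold, a constant of 32 added on the linear scale, random lists not matched on level, list means, and each list member left out in turn. One count without the genes of the 9 lists of other cell types was added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.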

Results

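Gene expression was measured in bone marrow derived macrophages, 1 control culture and 1 culture labelled beta-catenin deficient, each on 1 whole-transcript array. Beta-catenin links cadherins to the actin cytoskeleton and carries the canonical Wnt signal to the nucleus, and the comparison asks which macrophage genes differ when it is lacking, with adhesion and migration among the functions of interest. RMA values ranged from 2.70 to 14.1 in the control array and from 2.12 to 13.98 in the other, with medians of 7.31 and 7.24. Across all 25917 rows the arrays correlated with a Pearson r of 0.977 and a Spearman rho of 0.976, where rows are not independent replicates. Because each group had a single array, the values below carry no replicate error, and higher or lower describes these 2 arrays only.

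Ctnnb1, the gene of beta-catenin, was not lower in the array labelled deficient. Its level was 11.4 there against 11.3 in control, a difference of 0.15. The deleted exons are not given in the sources used here, and probes outside them check nothing about the deletion. Because the level was not lower, the sample is called the array labelled deficient throughout, and each direction below rests on that label. Axin2, a negative feedback regulator of Wnt signalling that is switched on by beta-catenin, was 1.64 lower, from 7.61 to 5.97, which put it below the floor of 7.28 in the array labelled deficient.

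Canonical Wnt target genes went both ways. Of 19 target genes at or above the floor, Axin2 among them, 3 were at least 1.5-fold higher, 2 at least 1.5-fold lower and 14 in between, and the list's median of -0.12 lay at percentile 32.7 of random lists. The lowest after Axin2 were Birc5, a mitotic survival gene that is also in the cell cycle list (-0.89), and Znrf3, a ubiquitin ligase that removes Wnt receptors (-0.56). The highest were Ccn5 (1.08), Nkd2 (0.81) and the AP-1 gene Fosl1 (0.61). Myc differed by -0.17 and Ccnd1 by -0.14 (both chosen after their values were seen). Among 32 components of the Wnt pathway, 4 were at least 1.5-fold higher and 0 lower, with a median of -0.02 (percentile 80.0) that turned to a positive value under centring, quantile normalization and loess, and a mean of 0.14, with which the list stood apart. The highest were the secreted Wnt antagonists Sfrp1 (2.54) and Sfrp2 (2.45), and the lowest were the receptor Fzd9 (-0.57) and the co-repressor Tle1 (-0.50). Fibroblast and stromal markers were also higher in the same array, with a median of 1.01.

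In all, 315 of the 10658 genes at or above the floor were at least 2-fold higher in the array labelled deficient and 169 were at least 2-fold lower. The highest 12 were led by Apod, a lipocalin (4.18), the membrane dipeptidase Dpep1 (3.70) and Kng1, the kinin precursor kininogen (3.36). They went on with Serping1, the C1 inhibitor (3.04), the Wnt antagonist Sfrp4 (3.02), the interferon-inducible Ifitm1 (3.01), the serpin Serpinb10 (from 6.20 to 9.20), the C-type lectin Clec10a (2.96), the chemokine Cxcl12 (2.87), Ly6i (2.69), Mamdc2 (2.68) and ceruloplasmin Cp (2.63). The lowest 12 spanned a narrower range. They were the histone gene H2bu2 (-1.98), Nptx1 (-1.90), the Ras exchange factor Rasgrp3 (-1.90), Tmem119 (-1.89), Nanos1 (-1.87), the dicarboxylate transporter Slc13a3 (-1.84), the histone gene H2bc3 (-1.81), Selenok (-1.79), the lubricin gene Prg4 (-1.74), the phosphatase Inpp4b (-1.73), the fatty acid receptor Gpr84 (-1.72) and the vault RNA Vaultrc5 (-1.71). Kng1, Ifitm1, Ly6i and the histone genes belong to families with close copies, so their probes may share signal. Of the higher genes, 114 had a control value below the floor, among them Apod (6.03), Dpep1 (7.16), Kng1 (5.85), Sfrp4, Serpinb10, Clec10a, Ly6i and Cp. Of the lower ones, 64 had a value below it in the array labelled deficient, among them H2bu2, Nptx1, Slc13a3, Selenok and Prg4. The size and rank of these differences depend on values in the dim range, where the arrays also differed across all genes. The same holds for each of the 182 named genes with a value below the floor, which were 27 in the control array and 19 in the array labelled deficient.

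The difference depended on level. The median over genes at or above the floor was -0.08, but it was -0.52 among the 540 genes with a mean level from 3 to 4 and -0.27 among the 2895 genes from 5 to 6. From 11 to 12 it was -0.00 (659 genes). Quantile normalization moved the median of all genes from -0.15 to -0.00. Higher genes made up 65.1% of the 2-fold genes in the main setting and 76.7% after a loess curve on level was subtracted (375 higher, 114 lower). The balance turned without a floor, where 43.1% were higher (352 against 465 lower), and at 1.5-fold, where 46.1% were higher (804 against 939 lower).

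**Figure D1:**
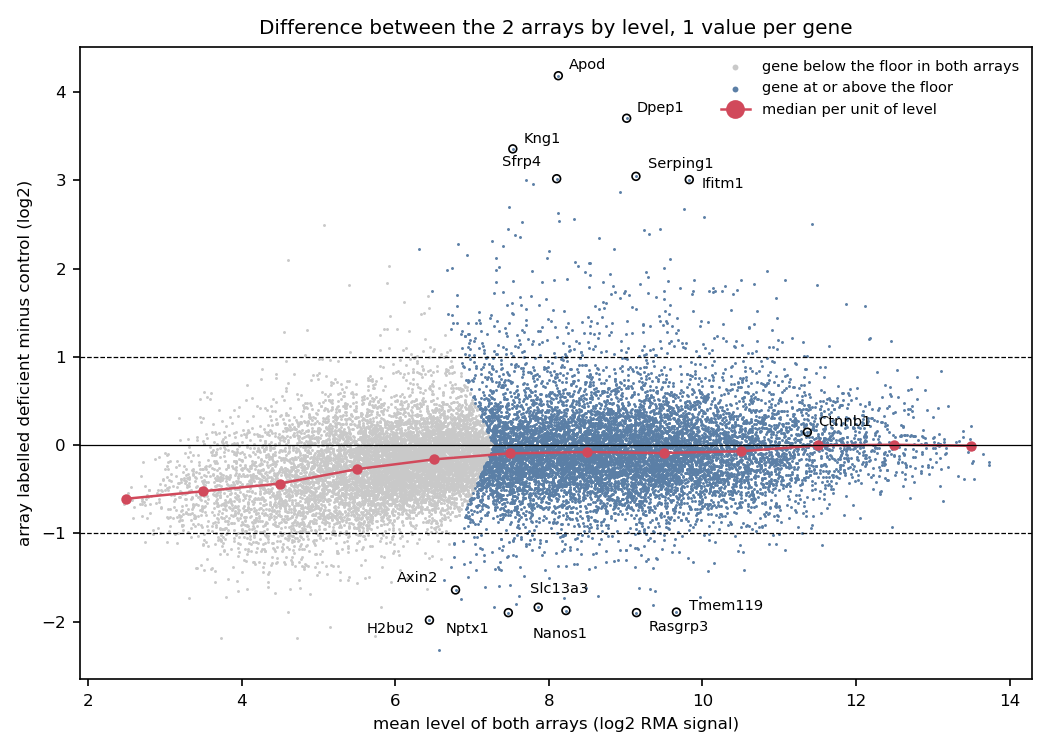
Difference between the arrays (array labelled deficient minus control, log2) against the mean level of both (log2 RMA signal), 1 point per gene, with the median per unit of level in red and dashed lines at 2-fold. Dim genes lay below 0, with a median of -0.52 between levels 3 and 4, Ctnnb1 lay near 0 at 0.15, and the higher genes reached 4.18 where the lowest labelled gene, H2bu2, was at -1.98.

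Genes of cell-to-cell adhesion were higher as a list. Of 17 cadherin and catenin genes, 5 were at least 1.5-fold higher and 1 lower, and the median of 0.44 stood apart at percentile 99.99. The highest were the mesenchymal cadherins Cdh2 (1.18) and Cdh11 (1.11) and the tight junction scaffold Tjp1 (0.75), and the lowest were Ctnnbip1, an inhibitor of beta-catenin (-0.63), Ctnnbl1 (-0.31) and Nectin1 (-0.13). Jup, the beta-catenin homologue plakoglobin, was 0.45 higher (chosen after its value was seen). The stromal markers, with their median of 1.01, were higher in the same array.

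Integrins and motility genes went both ways. Of 18 integrin genes, 4 were at least 1.5-fold higher and 3 lower, with a median of 0.04 (percentile 83.7). Itgax, the CD11c subunit of myeloid and dendritic cells, was 1.53 higher, followed by Itgad (0.92) and the platelet subunit Itga2b (0.83). Itgal, the alpha chain of LFA-1, was 1.29 lower, from 9.94 to 8.65, followed by Itga8 (-1.09) and Itga9 (-0.78). Itgad is read by 2 transcript clusters that disagreed, at 0.92 and -0.48. Of 43 genes of focal adhesions and the motile cytoskeleton, 7 were at least 1.5-fold higher and 4 lower, and the median of -0.04 (percentile 50.2) changed sign under centring and loess. Cortactin, Cttn (1.73), the actin regulator Evl (1.22) and the actin-bundling Fscn1 (1.18) were highest, while the parvin Parvb (-1.32), the kinase Rock1 (-0.85) and the Wiskott-Aldrich gene Was (-0.84) were lowest. Among 21 other adhesion receptors the median was 0.06 (percentile 88.8), with 2 genes at least 1.5-fold higher, Sdc1 (1.03) and Vcam1 (1.01), and 3 lower, of which Cadm1 (-1.38) and L1cam (-1.22) were the lowest.

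Matrix proteases and their inhibitors were higher, with 13 of 27 at least 1.5-fold higher and 0 lower (median 0.52, percentile 100). Collagenase Mmp13 (2.58) and Adamts1 (1.59) led, while Adam19 (-0.41) and Adam15 (-0.38) were lowest. Stromal markers (median 1.01) and neutrophil granule genes (median 1.17), which include Mmp8, were higher in the same array.

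Chemokines stood apart as well, with a median of 0.25 (percentile 99.7), 5 of 19 at least 1.5-fold higher and 3 lower. Cxcl12, the stromal ligand of Cxcr4 (2.87), the platelet chemokine Ppbp (2.51) and Ccl6 (1.60) were highest, and Ccl5 (-1.18), Ccl17 (-0.84) and Cxcl9 (-0.76) were lowest. Cxcl12 is also in the stromal list (median 1.01). Ppbp and Pf4 are also in the erythroid and megakaryocyte list, with a median of 0.49, 3 of 8 at least 1.5-fold higher and 3 lower, and a median of 0.0046 without a floor. The 19 chemoattractant receptors had a median of 0.10 (percentile 95.3), with 3 at least 1.5-fold higher and 5 lower. The monocyte receptor Ccr2 was 1.68 higher and Ccrl2 0.75 higher, while the purine receptor P2ry12 was 1.42 lower and Cxcr4 0.80 lower. Of 32 TGF-beta pathway genes, 6 were at least 1.5-fold higher and 4 lower (median -0.09, percentile 43.1, mean 0.02, with a median of 0.00 after loess). The ligand Bmp2 (1.73), the matrix protein Ltbp2 (1.46) and the co-receptor Tgfbr3 (1.18) were highest, and the receptors Bmpr2 (-0.88) and Tgfbr1 (-0.79) and the BMP target Id1 (-0.86) were lowest.

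**Figure D2:**
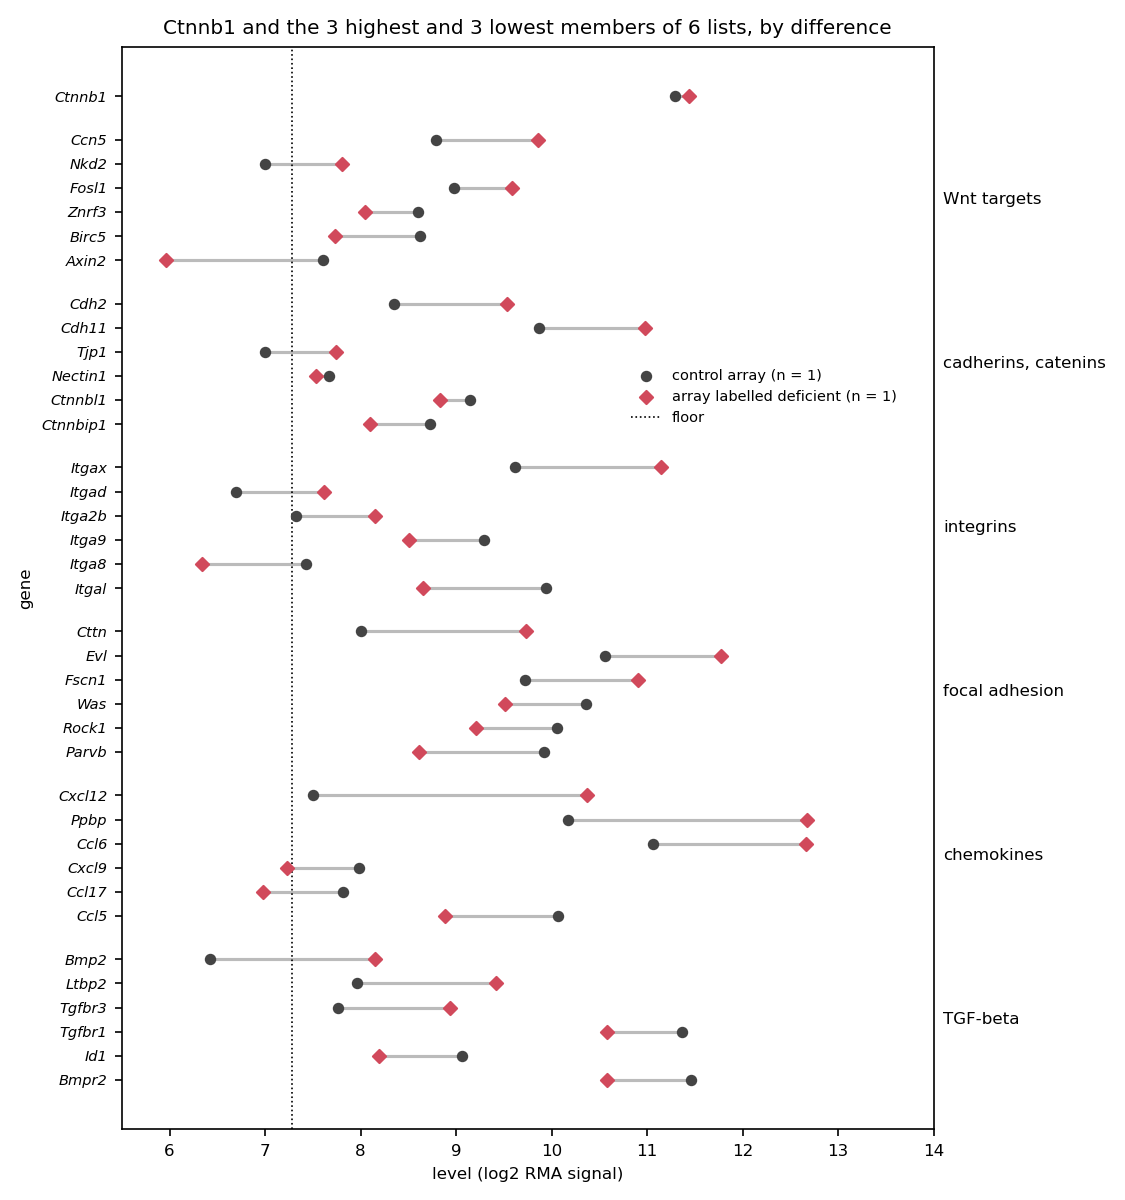
Level (log2 RMA signal) of Ctnnb1 and of the 3 highest and 3 lowest members of 6 lists in the control array (circles) and in the array labelled deficient (diamonds), 1 array each, with the floor as a dotted line. Axin2 was at 7.61 and 5.97 and Cxcl12 lay 2.87 higher, while Ctnnb1 was nearly level.

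Macrophage identity genes were nearly level between the arrays. Of 31, 25 lay within 1.5-fold, 4 were higher and 2 lower, with a median of 0.08 (percentile 93.4). The Fc receptors Fcgr4 (1.05) and Fcgr1 (0.78) were highest, and Lyz1 (-1.12) and the myeloid transcription factor Cebpa (-0.71) were lowest. The lysozyme genes Lyz1 and Lyz2 are close copies whose probes may share signal.

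Interferon-stimulated genes were higher as a list. Of 36, 26 were at least 1.5-fold higher, 10 within 1.5-fold and 0 lower, with a median of 0.68 (percentile 100). The immunity-related GTPase Iigp1 (2.22, from a control value of 5.20, below the floor) and the transcription factor Irf7 (1.78) were highest, and the smallest differences were those of Herc6 (0.07) and Slfn8 (0.23). Genes of MHC class II presentation had a median of 0.81 (percentile 100), with 4 of 8 at least 1.5-fold higher, led by H2-Aa (1.87) and H2-Ab1 (1.41). H2-Ob (-0.46) and the protease Lgmn (0.36) were lowest, and leaving out 1 member moved this median between 0.46 and 1.16. Dendritic cells also express MHC class II, and their markers had a median of 0.26 in the same array, with 4 of 15 at least 1.5-fold higher and 3 lower and a median of -0.22 without a floor. Genes of alternative activation stood apart with a median of 0.50 (percentile 100), 10 of 21 at least 1.5-fold higher and 2 lower. Clec10a (2.96) and arginase Arg1 (2.53), both below the floor in control, were highest, and Klf4 (-0.89) and Ccl17 (-0.84) were lowest. Stromal (median 1.01) and neutrophil granule markers (median 1.17) were higher in the same array as the interferon, MHC class II and alternative activation lists. Genes of classical activation had a median of 0.17 (percentile 99.3), with only 2 of 20 at least 1.5-fold higher, Cd86 (1.22) and Saa3 (0.98), and 3 lower, of which Cd40 (-0.85) and Tnf (-0.68) were lowest. This list no longer stood apart when its mean of 0.09 was used, and its median was -0.077 with a floor at the 75th percentile.

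Phagocytic and scavenger receptors had a median of 0.29 (percentile 99.99) over 29 genes, 5 at least 1.5-fold higher and 4 lower. Fcgr4 (1.05) and Cd209a (0.94) were highest, and the inhibitory receptor Havcr2 (-1.43) and Clec5a (-1.33) were lowest. Cd209a is also in the dendritic cell list, with a median of 0.26, 4 of 15 at least 1.5-fold higher and 3 lower. Markers of stromal cells (median 1.01) and neutrophil granules (median 1.17) were higher in the same array. Complement and acute phase genes had a median of 0.08 (percentile 84.0) over 11 genes, 4 at least 1.5-fold higher and 2 lower, with Serping1 (3.04) and haptoglobin Hp (1.94) highest and the complement regulators Cd59a (-1.09) and Cr1l (-0.77) lowest. This list stood apart by its mean of 0.47.

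Stromal, neutrophil and some mast cell markers were higher in the array labelled deficient, while erythroid, dendritic and endothelial markers went both ways. Of 29 fibroblast and stromal markers, 24 were at least 1.5-fold higher and 0 lower (median 1.01, percentile 100), led by Cxcl12 (2.87) and the growth factor receptor Pdgfra (2.12), with Mfap5 (-0.15) and Igfbp4 (-0.05) lowest. Igfbp4 changed sign under centring and loess. Of 20 neutrophil and granule genes, 15 were higher and 0 lower (median 1.17, percentile 100), led by Retnlg (2.57) and myeloperoxidase Mpo (2.22), with Camp (-0.43) and Cebpe (-0.10) lowest, and Cebpe changed sign under loess. Mast cell and basophil markers had a median of 0.64 over 6 genes (percentile 99.6), 3 at least 1.5-fold higher and 0 lower, with the basophil protease Prss34 (2.31) and carboxypeptidase Cpa3 (1.98), both below the floor in control at 6.11 and 5.68, highest and Hdc (0.02) and Srgn (0.32) lowest. Erythroid and megakaryocyte markers had a median of 0.49 over 8 genes (percentile 99.8), 3 at least 1.5-fold higher and 3 lower, with the platelet genes Ppbp (2.51) and Gp9 (1.29) highest and the erythroid gene Ermap (-0.90) and the transferrin receptor Tfrc (-0.63) lowest. Dendritic cell markers had a median of 0.26 over 15 genes (percentile 99.4), 4 at least 1.5-fold higher and 3 lower, from Itgax (1.53) and Kmo (1.30) down to Ccl17 (-0.84) and Cadm1 (-1.38). Endothelial markers had a median of 0.33 over 8 genes (percentile 97.9), 1 at least 1.5-fold higher and 1 lower, from Emcn (2.00) and Vwf (0.51) down to Ecscr (-0.14) and Flt1 (-0.67). Without a floor the dendritic cell (-0.22), mast cell and basophil (-0.040) and erythroid and megakaryocyte (0.0046) medians no longer stood apart, nor did the dendritic (0.042) and endothelial (0.27) medians with the floor on the mean or the means of the same lists (0.19 and 0.38). Leaving out 1 member moved the mast cell and basophil median between 0.35 and 0.92.

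Lymphocyte and osteoclast lists did not stand apart at the floor of 7.28. T and NK cell markers had a median of 0.28 over 6 genes (percentile 93.3), 1 at least 1.5-fold higher and 1 lower, with Nkg7 (1.09) and Lat (0.56) highest and Cd5 (-1.21) and Cd4 (0.15) lowest, but without a floor the median was -0.40 and stood apart lower. B cell markers had a median of 0.19 over 5 genes (percentile 89.9), 0 of them 1.5-fold apart, with Ebf1 (0.58) and Cd79b (0.32) highest and Blnk (-0.45) and Vpreb2 (-0.35) lowest. The 16 osteoclast genes had a median of 0.12 (percentile 95.7), 4 at least 1.5-fold higher and 0 lower, with the proton pump subunit Atp6v0d2 (1.81) and Mmp9 (1.07) highest and Ocstamp (-0.43) and Nfatc1 (-0.43) lowest.

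**Figure D3:**
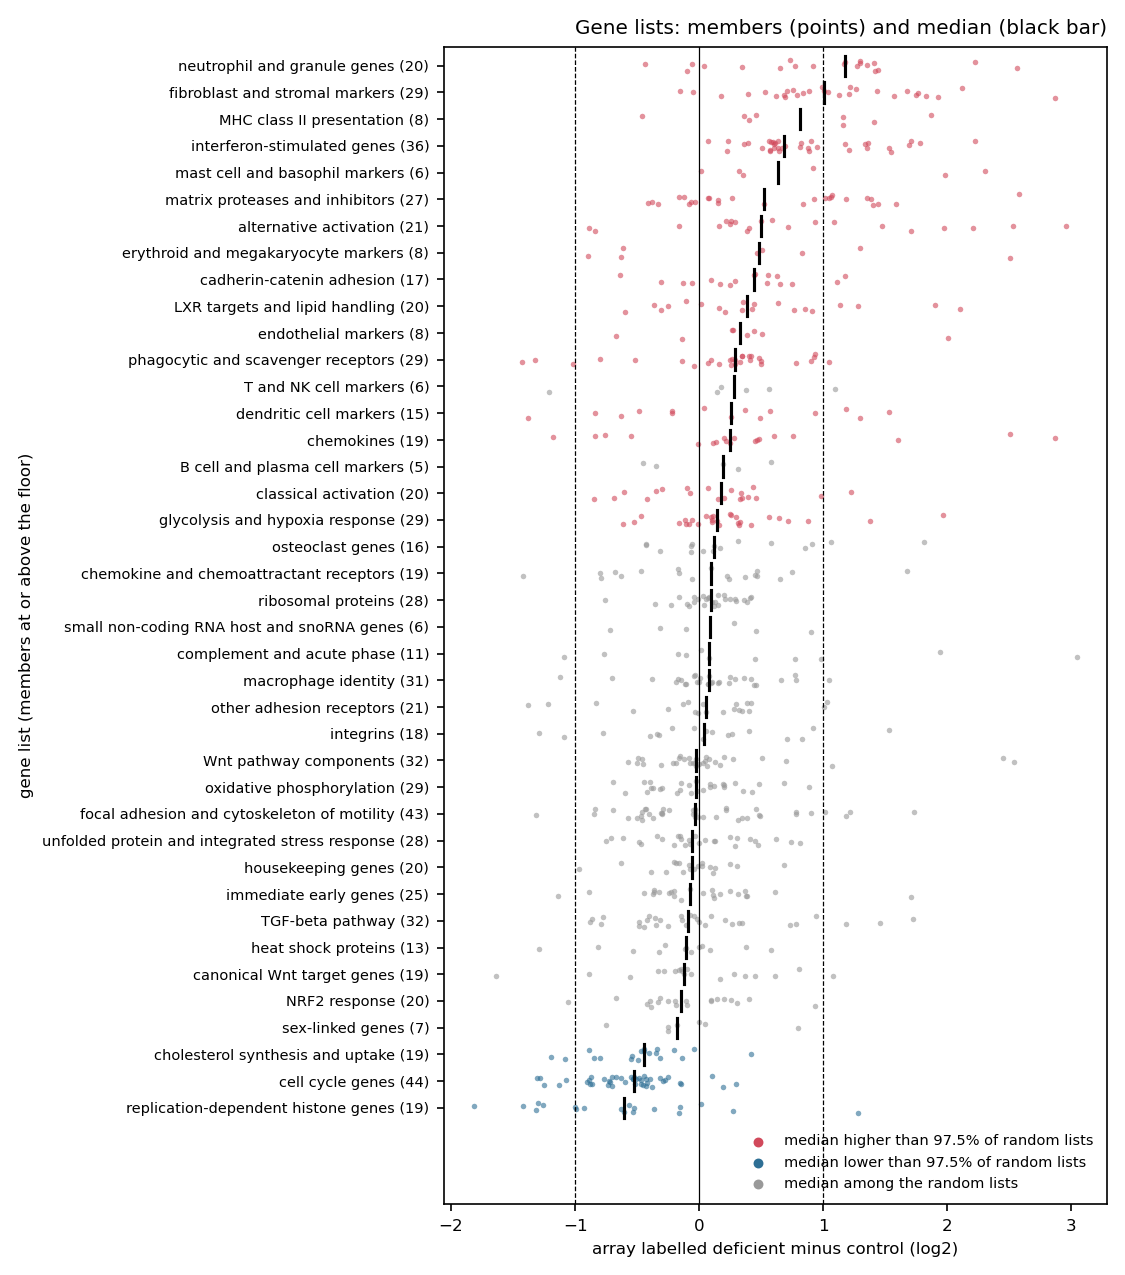
Difference (array labelled deficient minus control, log2) of each member at or above the floor (points) and the median (black bar) for the 40 gene lists, coloured by whether the median stood apart from random lists. Neutrophil granule genes (1.17) and stromal markers (1.01) had the highest medians, and histone (-0.60), cell cycle (-0.53) and cholesterol genes (-0.45) the lowest.

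Proliferation genes were lower. Of 44 cell cycle genes, 19 were at least 1.5-fold lower and 0 higher (median -0.53, below all 10000 random lists). The cohesin acetyltransferase Esco2 (-1.30) and the mitotic kinesin Kif11 (-1.28) were lowest, and E2f1 (0.30) and Rrm2 (0.19) were the highest members. Replication-dependent histone genes were lower too, with 10 of 19 at least 1.5-fold lower and 1 higher (median -0.60, also below all random lists). H2bc3 (-1.81) and H4c6 (-1.42) were lowest, and H2bc8 (1.28) and H2ac4 (0.27) highest. In the same array stromal (median 1.01) and neutrophil granule markers (median 1.17) were higher.

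Lipid genes split. Genes of cholesterol synthesis and uptake had a median of -0.45 (percentile 0.01), with 5 of 19 at least 1.5-fold lower and 0 higher. Lanosterol demethylase Cyp51 (-1.19) and the sterol reductase Tm7sf2 (-1.08) were lowest, and Ebp (0.42) and Fdps (-0.04) highest. Fdps changed sign under centring, quantile normalization and loess. LXR targets and lipid handling genes had a median of 0.39 (percentile 100), with 8 of 20 at least 1.5-fold higher and 1 lower. The fatty acid binding protein Fabp4 (2.11) and the desaturase Scd1 (1.90) were highest, and fatty acid synthase Fasn (-0.59) and Pltp (-0.36) lowest. Stromal (median 1.01) and neutrophil granule markers (median 1.17) were higher in the same array.

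Glycolysis and hypoxia genes had a median of 0.14 (percentile 99.5) over 29 genes, 5 at least 1.5-fold higher and 1 lower, with adrenomedullin Adm (1.97) and Vegfa (1.38) highest and Pkm (-0.61) and Aldoc (-0.53) lowest. The 2 transcript clusters of Pkm differed, at -0.61 and -0.19. Markers of stromal cells (median 1.01) and neutrophil granules (median 1.17) were higher in the same array. The remaining lists did not stand apart. Oxidative phosphorylation had a median of -0.02 over 29 genes, from Etfa (0.88) and Sdha (0.68) to Cox4i1 (-0.69) and Uqcrq (-0.60). The NRF2 response had a median of -0.15 over 20 genes, from Gstp1 (0.94) and Prdx1 (0.40) to Gsta3 (-1.06) and Gclm (-0.67). The unfolded protein and integrated stress response had a median of -0.05 over 28 genes, from Pdia6 (0.81) and Nupr1 (0.74) to Dnajb9 (-0.75) and Edem1 (-0.71). Heat shock proteins had a median of -0.10 over 13 genes, from Hspa1a (0.58) and Bag3 (0.38) to Hspb1 (-1.29) and Chordc1 (-0.82). Immediate early genes had a median of -0.08 over 25 genes, from Egr2 (1.71) and Fosl1 (0.61) to Fosb (-1.14) and Klf4 (-0.89). The medians of the oxidative phosphorylation, stress response and immediate early lists changed sign under a scaling alternative.

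The control lists did not stand apart in the main setting. Ribosomal protein genes had a median of 0.09 over 28 genes (percentile 95.3), from Rpl6 (0.42) and Rps20 (0.41) to Rpl14 (-0.76) and Rps6 (-0.35), and this list stood apart higher after quantile normalization (0.16) and against unmatched random lists (percentile 98.1). Housekeeping genes had a median of -0.06 over 20 genes (percentile 29.2) that changed sign under centring, from Sdha (0.68) and Psmb2 (0.31) to Polr2a (-0.97) and Tfrc (-0.63). Small non-coding RNAs and their hosts had a median of 0.09 over 6 genes, from Gas5 (0.90) and Malat1 (0.46) to Terc (-0.72) and Snhg5 (-0.31), and the 4 transcript clusters of Gas5 ran from -1.13 to 1.08. Sex-linked genes had a median of -0.18 over 7 genes, from Eif2s3y (0.79) and Eif2s3x (0.05) to Kdm6a (-0.75) and Uty (-0.25). The Y-linked Eif2s3y (9.12 and 9.92) and Uty (9.43 and 9.18) were above the floor in both arrays, and Xist (chosen after its values were seen) was at 5.55 and 5.47, below it.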

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

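Outside the named genes, the table held 4285 rows with several gene symbols or none, which enter no comparison above. Of the 1928 such rows at or above the floor, 48 were at least 2-fold higher in the array labelled deficient than in control, which is what drew attention to them, and 35 were at least 2-fold lower. For comparison, 315 (2.96%) of the 10658 genes at or above the floor were at least 2-fold higher and 169 (1.59%) at least 2-fold lower. Higher rows were thus no more frequent than higher genes, and lower rows were slightly more frequent than lower genes.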

How the results depend on the processing

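The count without genes of the other cell type lists was chosen after seeing the data. With 1 array per group, no replicate could be left out. No paired analysis was possible because each group had 1 sample. The counts of 315 higher and 169 lower genes became 184 and 72 with a floor at the 75th percentile, 804 and 939 at 1.5-fold, and 102 and 22 at 3-fold, where fewer or more genes pass by construction. The lower count moved to 465 without a floor, where dim genes enter, and to 109 with a constant of 32 added. The remaining counts stayed within 1.5 times, including 278 and 167 without genes of the other cell type lists. Those lists held only 37 of the 315 higher and 2 of the 169 lower genes, so leaving them out could hardly move the counts. Other genes of such cells stayed in, among them Prrx1 (1.85) and Pcolce (1.79) of the second stromal list described below. The counts therefore do not show that the higher genes are free of transcripts of other cell types. Ctnnb1 ranged from 0.13 to 0.23. Of 1370 values of 182 named genes under alternatives, 15 dropped below 2-fold, 11 passed it, and 0 of those past 2-fold in the main setting changed sign. Of the 19 lists that stood apart, 14 did so under each alternative run for them.

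Of 469 values of the lists under alternatives, 448 kept their call, and 5 changed sign in a list that stood apart before or after. The 5 were the T and NK cell (-0.40), dendritic cell (-0.22) and mast cell and basophil medians (-0.040) without a floor, the classical activation median (-0.077) with a floor at the 75th percentile, and the mean of the Wnt components (0.14). Of these, the T and NK cell list and the Wnt components stood apart under the alternative and the others no longer did. A further 6 values lost the call in the same direction: erythroid and megakaryocyte markers without a floor (0.0046), dendritic (0.042) and endothelial markers (0.27) with the floor on the mean, and the means of classical activation (0.090), dendritic (0.19) and endothelial markers (0.38). Another 10 gained it: other adhesion receptors without a floor (0.19) and at the 75th percentile (0.19), osteoclast genes without a floor (0.13) and by their mean (0.29), complement without a floor (0.26), by its mean (0.47), after quantile normalization (0.30) and after loess (0.31), and ribosomal proteins after quantile normalization (0.16) and against unmatched random lists (0.094). The cause was not tested for any list. The B cell list had under 5 members after quantile normalization and loess and has no value there, and counting each transcript cluster was run for the gene counts alone.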

Other observations

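The test of the cell cycle genes against macrophage identity genes was chosen after the result was seen, and the genes of the next paragraph were picked after their values were seen.

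Single genes outside the fixed lists or apart from their list, with no group tested, also differed. The array labelled deficient was higher for Plac8 (1.96), Ly6i (2.69), the chemokine receptor Ccr2 (1.68), the kininogens Kng1 (3.36) and Kng2 (2.38), the coagulation factor F10 (2.06), and the secreted factors Fgf7 (2.40), Rspo2 (2.03) and Stc1 (2.26). The fractalkine receptor Cx3cr1 differed by -0.68, P2ry12 by -1.42 and Tmem119, a marker of microglia, by -1.89.

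Stromal and neutrophil markers were higher in the array labelled deficient. The stromal members brightest there, picked after their values were seen, were Thbs1 (a difference of 0.40), Acta2 (0.62), Igfbp7 (1.57), Bgn (1.21), Ccn2 (1.21) and Sparc (0.83). These members were bright in the control array too, at levels from 11.3 (Igfbp7) to 12.7 (Thbs1). Also in other lists are 3 stromal markers (Cxcl12, Vcam1, Thy1). Median differences per unit of level ran from -0.61 to 0.0043, so the trend with level did not point towards higher stromal markers. Subtracting it could hardly lower the stromal median, which was 1.10 after loess (95% bootstrap interval over genes 0.85 to 1.36). The loess result is therefore no further test of this cause. A larger share of stromal cells in that culture is a candidate explanation: a second stromal list, written down before its values were examined and sharing Ccn5 with the Wnt targets, had a median of 0.97 over 35 genes (0.67 to 1.27), 27 at least 1.5-fold higher and 1 lower. For granulocytes a second list had a median of 0.15 over 23 genes (-0.19 to 0.35). It shares Nkg7 with the T and NK cell markers and Cd63 with the other adhesion receptors. Whether its members are specific to granulocytes in this culture was not checked. Of these genes, 6 were at least 1.5-fold higher and 4 lower. Its percentile of 99.3 met its part of the prediction, but its median fell short of the predicted 0.5. The median lay below 0.25, so the bound set beforehand against this explanation was met. The interval over genes crossed 0.25, but it was not part of that rule. It treats genes as independent and does not measure a spread between cultures. By the rule, the second list thus went against a larger share of granulocytes. From 1 pair of arrays it neither excludes such a share nor tells it apart from a difference in granule genes alone. An effect of beta-catenin on these genes within macrophages stays open and untested, as bulk RNA does not place a transcript in a cell.

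Cell cycle genes had a median difference of -0.53. Dilution of cycling macrophages by non-cycling stromal cells would lower macrophage identity genes by about as much, but the interval of their median of 0.08 ran from -0.020 to 0.24. This comparison was chosen after the result was seen. It also takes the identity genes to be absent from stromal cells and the stromal cells not to cycle. Neither was checked, so the comparison does not exclude dilution. From level 8 to 11 the median difference of all genes was between -0.09 and -0.07 per unit of level. Subtracting a trend of that size could not remove a median of -0.53, and the cell cycle median was -0.44 after loess (-0.61 to -0.38). The loess result was thus fixed by the size of the trend and tests nothing further. Slower proliferation with beta-catenin deficiency and a difference in density or age between 2 single cultures both stay open and were not tested.

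Dim genes were lower in the array labelled deficient. Over all rows the 1st percentile was 3.04 there against 3.59 in control, the 5th 4.06 against 4.58 and the 25th 5.83 against 6.10. The 95th percentile was 11.3 in both, so the columns did not share 1 distribution at the low end. These percentiles describe the same dim rows and are no separate test of a cause. A loss of weak transcripts from the cells was predicted to leave olfactory and vomeronasal receptor genes, which serve sensory neurons, near 0. That prediction failed: 91.7% of these 1211 rows were lower, with a median of -0.53 and an upper bootstrap bound of -0.50. A different background or a separate normalization run of the columns predicted a median within 0.1 of that of other genes matched on level, but these were at -0.33, so this explanation was met only in its sign and stays open. The same gap of more than 0.1 means that the bound written against a loss of transcripts was met in its first part alone. By the rule set beforehand, a loss of transcripts among other dim genes therefore stays undecided.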
